A study of Mus musculus with 6 samples.

How the data were processed

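Cerebral cortex was dissected from 3 wild type and 3 Fezf2 KO mice at postnatal day 0, and total RNA of each brain was made into 1 Illumina TruSeq library and sequenced on a Genome Analyzer II, per the labels. The submitters' processing notes name Bowtie, STAR, DESeq and the mouse build mm9, with no versions or settings. The deposited signal was a table of 23016 genes, with read counts per gene divided by 1 size factor per library in the manner of DESeq and rounded, scaled neither to library size in reads per fixed total nor to gene length. It held 19192 clustered known genes, 3819 assembled long noncoding transcripts and 5 other entries, of which 642 shared a symbol with another entry and 203 were 0 in all libraries. Some entries overlap: 5930412G12Rik and linc-Fzd10-BP held identical values, so that locus counts more than once. The strand of the libraries is not stated, so values of overlapping genes, antisense transcripts and multi-copy families are uncertain.

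The smallest step between values of a library was taken as the value of 1 read, from 0.812 to 0.936, and 100% of the values of each library were whole multiples of it within 0.006. Dividing by it gave back whole reads, 44978380 to 52872577 per library. A count of 0 allows up to 3 reads (2.44 to 2.81 deposited units). Such limits cover counting error only, since reads of the same molecule cannot be told from one another. Pairs of libraries differed by 8.85 to 33.0 in chi-square per degree of freedom, so no library was a resampling of another.

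The gene test, its threshold, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The design assumed counts and a quasi-likelihood fit in edgeR; because the table held values already divided by size factors, its stated substitute, limma on log2(value + 1), was used, and edgeR on the recovered reads became an alternative. Genes with a deposited value of at least 10 in at least 3 libraries were tested (17557), genotype was the single term, and the variance was moderated with a trend. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

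The steps were tested on simulated data with 200 genes changed by 1.5-fold or 2-fold, in 5 runs. Limma recovered 50.4% of the smaller and 77.6% of the larger changes, with 7.5% false among the genes called, and edgeR recovered 50.6% and 78.0% with 8.4% false. On the real recovered reads edgeR called 121 genes.

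The named genes were Fezf2, then the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 50 reads and no overlap between genotypes, then up to 4 changed members of each list with the smallest p, or up to 2 members, given as values, where none changed. Predicted genes count in totals and are not named by the rule. The 26 lists were layer 5 subcerebral, layer 6 corticothalamic, callosal and upper-layer, subplate, Cajal-Retzius, interneuron, axon guidance, glutamatergic, voltage-gated channel, neuropeptide, radial glia, intermediate progenitor, oligodendrocyte, astrocyte, microglia, endothelial, meningeal, choroid plexus, erythroid, striatal, thalamic, hippocampal, olfactory bulb, immediate early, hypoxia and heat shock genes. Each was tested with camera at a preset correlation of 0.01 and adjusted over the 26 lists, and again with an estimated correlation, with which 0 lists passed (lowest adjusted p 0.0698). The fry rotation test passed 2 lists, corticothalamic and subplate genes. Some genes stand in more than one list, as Slc17a6, Trh, Npy, Penk and Tac1 do. For the genes near Fezf2, 91.4% of the clustered known genes were matched by symbol to the GRCm38 annotation, which served for names and neighbours only.

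Alternatives were a pseudocount of 0.5 in place of 1, no filter, edgeR with TMM, RLE or upper quartile factors, DESeq2, limma-voom, litter as a replicate block, litter m1 alone, each library left out in turn, a minimum change of 1.2-fold, an adjusted p threshold of 0.1, and Fezf2 and sex-linked genes left out. Litter m1 gave replicates 1 and 2 of each genotype and m2 gave replicate 3. As a check on litter, each library's deviation from its genotype mean was correlated between genotypes over 13558 genes, which are not independent replicates. Pearson's r was between -0.135 and 0.254 for the 5 pairs of libraries from the same litter and between -0.189 and -0.033 for the 4 pairs from other litters. No fit within litter m2 was possible with 1 library per genotype. Isoforms, variants and sequence reads were not analysed here.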

Results

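Total RNA from dissected cerebral cortex of 6 newborn mice (postnatal day 0) was sequenced, 3 wild type pups and 3 Fezf2 KO pups, with 1 library from each brain. Fezf2 encodes a zinc finger transcription factor of deep-layer cortical neurons that is needed to specify subcerebral projection neurons. The comparison asks which transcripts differ between newborn cortex with and without an intact Fezf2 gene. In both genotypes replicates 1 and 2 came from litter m1 and replicate 3 came from litter m2. The gene reads recovered from the deposited values were 44978380 in wild type 1, 48331637 in wild type 2 and 49139392 in wild type 3. They were 52872577 in Fezf2 KO 1, 47169514 in Fezf2 KO 2 and 47951743 in Fezf2 KO 3. Levels are normalised read counts per library (mean ± SD, n = 3 in each genotype). Changes are log2 ratios of Fezf2 KO to wild type, computed on the normalised count plus 1, which understates the fold of genes with few reads.

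Fezf2 fell from 5452 ± 452 in wild type to 1633 ± 318 in Fezf2 KO cortex (log2 -1.75, SE 0.129, limma adjusted p = 0.000832). Reads of the gene remained in each Fezf2 KO library, from 1377 to 1989, against 5030 to 5928 in wild type, and the part of the gene that the allele lacks is not given in the sources used here. Among 17557 genes tested with limma, 125 (0.7%) changed, 71 higher and 54 lower in Fezf2 KO cortex. Of these, 21 rose and 33 fell by at least 2-fold. In 100% of the changed genes all libraries of one genotype lay above all of the other, as they did in 14.5% of the genes tested, where chance gives 10%. The test favours such genes, so the 100% is no support of its own. The number of changed genes varied with the library left out, and fewer libraries alone can lower it. It was 95, 77 and 74 without wild type 1, 2 and 3, and 108, 119 and 61 without Fezf2 KO 1, 2 and 3. The higher genes numbered 55, 40 and 34 without wild type 1, 2 and 3, and 50, 46 and 21 without Fezf2 KO 1, 2 and 3. In litter m1 alone, with 2 libraries per genotype, limma called 29 genes and gave Fezf2 a log2 change of -1.72 with an adjusted p of 0.0595, while DESeq2 on the recovered reads of all libraries called 403.

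The highest rise was that of Pax7, a paired-box transcription factor of the dorsal neural tube and midbrain, from 1.21 ± 1.05 in wild type (4 reads in all 3 libraries together) to 305 ± 29.6 in Fezf2 KO cortex (log2 7.26, SE 0.401, limma adjusted p = 0.00015). Figf, which encodes the growth factor VEGF-D, rose from 114 ± 13.7 to 940 ± 205 (log2 3.02, SE 0.163, limma adjusted p = 0.000146). Fosl2, an AP-1 transcription factor, rose from 3815 ± 326 to 10090 ± 451 (log2 1.41, SE 0.068, limma adjusted p = 7.24e-05). Unc13c, a synaptic vesicle priming protein, reached 912 ± 88.9 against 299 ± 41.0, and Cck, the neuropeptide cholecystokinin, reached 7926 ± 693 against 3373 ± 450. Scg2, which encodes secretogranin II of dense core vesicles, reached 5575 ± 1166 against 2029 ± 467. The other named rises were those of Slc24a2 (log2 1.28), the luteinising hormone receptor gene Lhcgr (1.49), the adrenergic receptor gene Adra1d (1.47), the matrix gene Matn2 (1.44), Tll2 (1.37) and the Wnt receptor gene Fzd10 (1.35). Among these, limma's adjusted p rose above 0.05 for Lhcgr (0.0521) and Matn2 (0.0587) without Fezf2 KO 3. For Adra1d it was 0.0627 without wild type 1, and 0.0676, 0.0957 and 0.144 without Fezf2 KO 1, 2 and 3. For Fzd10 it was 0.0889 without wild type 3, and 0.0575, 0.0743 and 0.137 without Fezf2 KO 1, 2 and 3. Tll2 (limma adjusted p = 0.0445, edgeR 0.0507) stayed under 0.05 when Fezf2 KO 3 was left out and lay between 0.0641 and 0.154 without wild type 1, 2 or 3 or Fezf2 KO 1 or 2.

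The largest named falls were those of Ngfr, the low-affinity neurotrophin receptor, from 1256 ± 214 to 151 ± 17.3 (log2 -3.04, SE 0.141, limma adjusted p = 6.02e-05), and of Nxph3, a neurexin ligand, from 6199 ± 255 to 787 ± 151 (log2 -2.99, SE 0.123, limma adjusted p = 3.63e-05). Cplx3, a complexin of subplate neurons, fell from 378 ± 79.9 to 59.8 ± 7.52 (log2 -2.62, SE 0.184, limma adjusted p = 0.000723). Other named falls were those of Tcerg1l (log2 -1.83), the heparan sulfate sulfotransferase genes Hs3st3b1 (-1.82) and Hs3st6 (-1.73), the cardiac myosin gene Myh6 (-1.94) and Clic5 (-1.70). Zfpm2, Syt6, Foxp2 and Tle4, which are among the 12 largest named falls, belong to the corticothalamic genes. Hs3st6 had limma adjusted p of 0.058 without wild type 1 and 0.0824 without wild type 3.

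**Figure D1:**
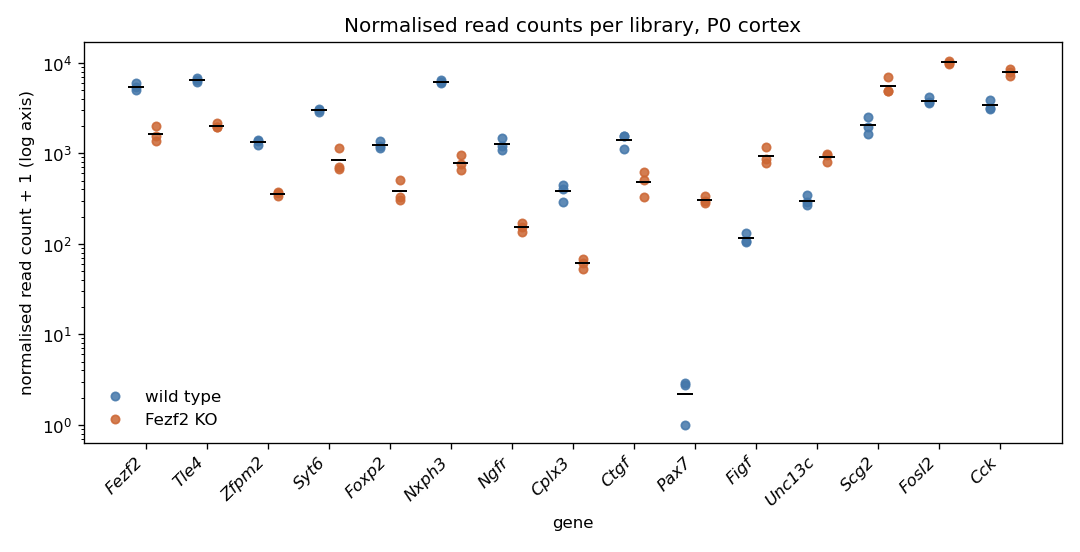
Normalised read count plus 1 (log axis) of 15 genes in each library, with wild type in blue and Fezf2 KO in orange; points are libraries and bars are means of 3. Tle4 lay between 6188 and 6772 in wild type and between 1933 and 2134 in Fezf2 KO libraries.

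Genes of layer 6 corticothalamic neurons, which send axons to the thalamus, were lower as a group by camera with a preset correlation of 0.01 (adjusted p = 1.1e-13, and adjusted p = 0.0698 with an estimated correlation). Of 15 tested, 6 fell, 0 rose and 9 did not pass (8 lower and 0 higher adjusted over the list alone), with a median log2 of -0.23. Leaving out 1 library gave 5 to 7 falls, with Grik3 lost without wild type 2 and without Fezf2 KO 3. Without both wild type 1 and Fezf2 KO 1, an alternative chosen after seeing the data, 3 fell (Tle4, Zfpm2 and Syt6). Tle4, a Groucho-family corepressor, fell from 6457 ± 295 to 2003 ± 114 (log2 -1.69, SE 0.061, limma adjusted p = 3.63e-05). Foxp2, a forkhead transcription factor, fell from 1236 ± 107 to 379 ± 115 (log2 -1.74, SE 0.187, limma adjusted p = 0.00594). Zfpm2, a cofactor of GATA factors, fell from 1326 ± 90.2 to 356 ± 16.6, and Syt6, a synaptotagmin, fell from 2978 ± 96.6 to 838 ± 263. Ppp1r1b (log2 -1.32), which striatal neurons also express, and Grik3 (-0.40) fell too, whereas Tbr1 (0.05), Sox5 (-0.01) and Ntsr1 (-0.09) did not pass the test. With the mean of the striatal genes as a covariate in limma, the log2 change of Foxp2 went to -1.24 and that of Syt6 from -1.87 to -1.41. Those of Tle4 (-1.60) and Zfpm2 (-1.89 to -1.83) moved less. The fry rotation test, which asks whether the genes of a list move one way and does not compare them with other genes, gave an adjusted p of 0.00305.

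Subplate genes, which mark the early-born neurons under layer 6, were lower as a group by camera (adjusted p = 3.09e-07, and adjusted p = 0.121 with an estimated correlation; fry gave 0.0149). Of 12 tested, 5 fell and 0 rose (6 lower and 1 higher adjusted over the list alone). Besides Cplx3, Nxph4, a second neurexophilin, fell from 2020 ± 21.0 to 1038 ± 116 (log2 -0.97, SE 0.086, limma adjusted p = 0.00237). Ctgf, a secreted matricellular protein, fell from 1403 ± 258 to 482 ± 146 (log2 -1.57, SE 0.229, limma adjusted p = 0.0243). Its reads are uncertain in origin, because an assembled transcript antisense to Ctgf overlaps it and the strand of the library is not stated. Tmem163 (log2 -0.61) and Trh (-1.20) fell as well, while Nr4a2, with 7343 ± 206 against 4835 ± 1288, did not pass (limma adjusted p = 0.237). With litter as a block in limma 4 members fell, and Trh had an adjusted p of 0.0578. Counts of lower members were 2 without wild type 1, 2 without wild type 3, 3 without Fezf2 KO 2 and 3 without Fezf2 KO 3, and without wild type 3 limma also called 1 member, Nr4a2, higher. Limma's adjusted p of Ctgf was 0.08 without wild type 1, 0.117 without wild type 3 and 0.0508 without Fezf2 KO 2. That of Tmem163 was 0.0726, 0.0609 and 0.0723 without wild type 1, 2 and 3 and 0.0812 without Fezf2 KO 3.

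Layer 5 subcerebral projection neuron genes, whose neurons project to the brainstem and spinal cord, were lower as a group by camera (adjusted p = 0.000642, and adjusted p = 0.381 with an estimated correlation). Of 21 tested, 0 fell by limma (8 had an unadjusted p under 0.05 and a lower value, and by edgeR 0 and by DESeq2 3 were lower), and 1 rose; adjusted over the list alone 8 were lower and 1 higher. The gene that rose was Otx1, a homeobox gene of deep-layer neurons, from 1625 ± 8.34 to 2442 ± 303 (log2 0.58, SE 0.091, limma adjusted p = 0.035). Bcl11b, the transcription factor CTIP2, had 7468 ± 2132 against 13030 ± 1519 (log2 -0.84, SE 0.182, limma adjusted p = 0.114). Crym, a thyroid hormone binding protein, had 641 ± 454 against 2218 ± 344 (log2 -2.22, SE 0.655, limma adjusted p = 0.278). The mean of the centred log2 values of the list was -0.35, 0.05 and -0.17 in Fezf2 KO 1, 2 and 3, against 0.22, 0.19 and 0.06 in wild type 1, 2 and 3, so Fezf2 KO 2 lay near wild type 3. Striatal genes were also nearest to wild type in Fezf2 KO 2, and with their mean as a covariate in limma the log2 change of Bcl11b went to -0.29 (SE 0.061) and that of Crym to -0.51 (SE 0.533). Limma's adjusted p of Otx1 was 0.106, 0.117 and 0.126 without wild type 1, 2 and 3, 0.0885 and 0.141 without Fezf2 KO 1 and 3, and it was 0.0514 by edgeR with litter as a block. Without Fezf2 KO 1, 2 members were lower (Crym and Pex5l), and without Fezf2 KO 2, 2 members were lower (Bcl11b and Pex5l).

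Genes of striatal neurons, from the tissue under the cortex, were lower as a group by camera. It gave their 12 tested members an adjusted p of 5.11e-10 (median log2 -1.31), and adjusted p = 0.34 with an estimated correlation. By limma 0 changed over all genes, with 11 at an unadjusted p under 0.05, 11 lower adjusted over the list alone, 0 by edgeR and 1 (Penk) by DESeq2. Penk, which encodes enkephalin, had 206 ± 87.2 against 514 ± 158 (log2 -1.35, SE 0.307, limma adjusted p = 0.133), and Six3 had 186 ± 122 against 433 ± 95.2 (log2 -1.38, SE 0.382, limma adjusted p = 0.243). The mean of the centred log2 values of the list was 0.91, 0.57 and 0.37 in wild type 1, 2 and 3, and -1.55, 0.36 and -0.66 in Fezf2 KO 1, 2 and 3. For the corticothalamic genes this mean was -0.34, -0.24 and -0.40 in Fezf2 KO 1, 2 and 3, against 0.36, 0.34 and 0.28 in wild type 1, 2 and 3. For the subplate genes it was -0.40, -0.28 and -0.24, against 0.44, 0.26 and 0.23. Without Fezf2 KO 2, 6 striatal members were lower by limma, Penk (adjusted p = 0.0358) and Six3 (0.0079) among them.

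**Figure D2:**
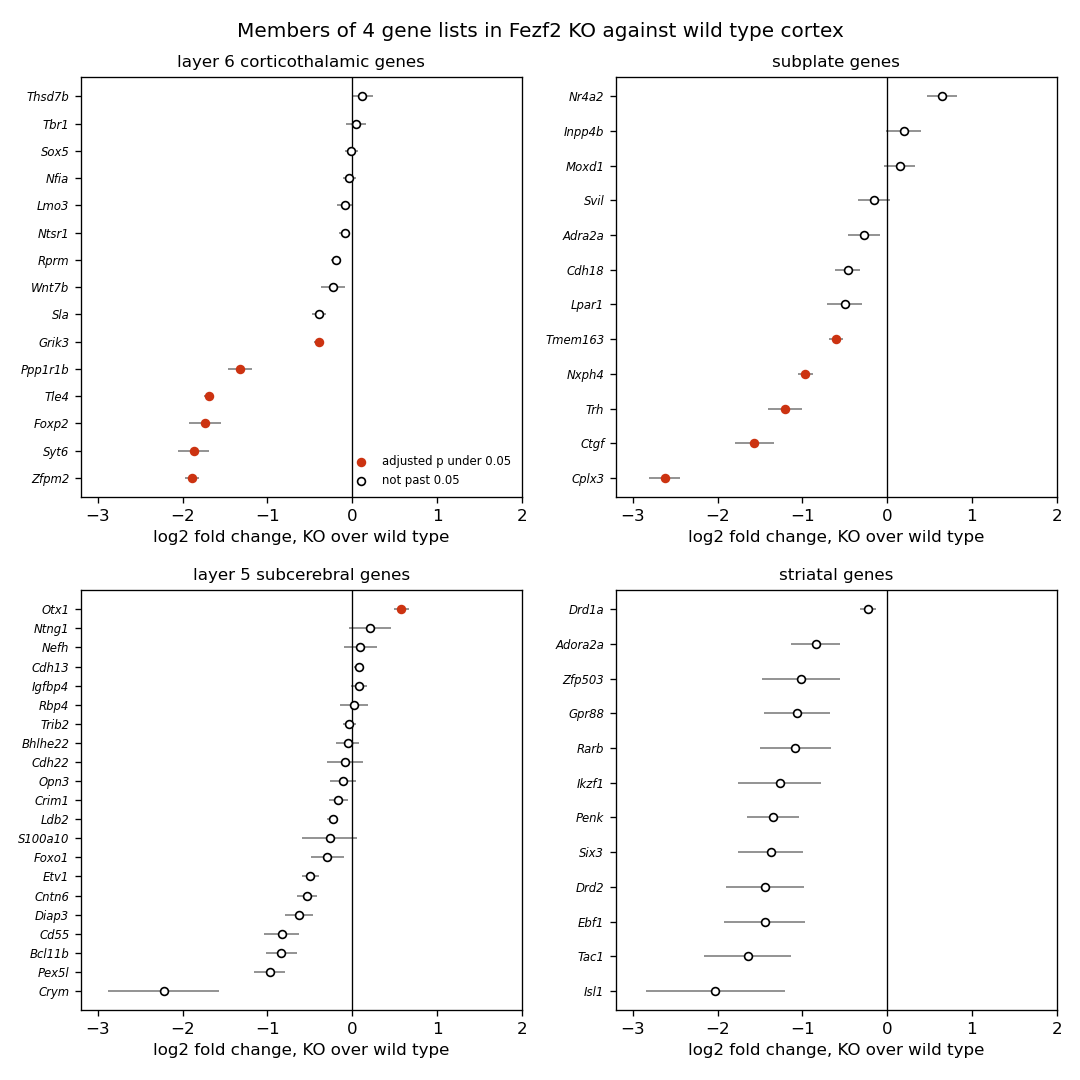
Log2 change of each tested member of 4 gene lists, Fezf2 KO over wild type (3 libraries each), with standard errors as bars; filled points have a limma adjusted p under 0.05. Cplx3 lies lowest among the subplate genes at -2.62, and Isl1 lowest among the striatal genes at -2.03 with a wide error of 0.818.

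**Figure D3:**
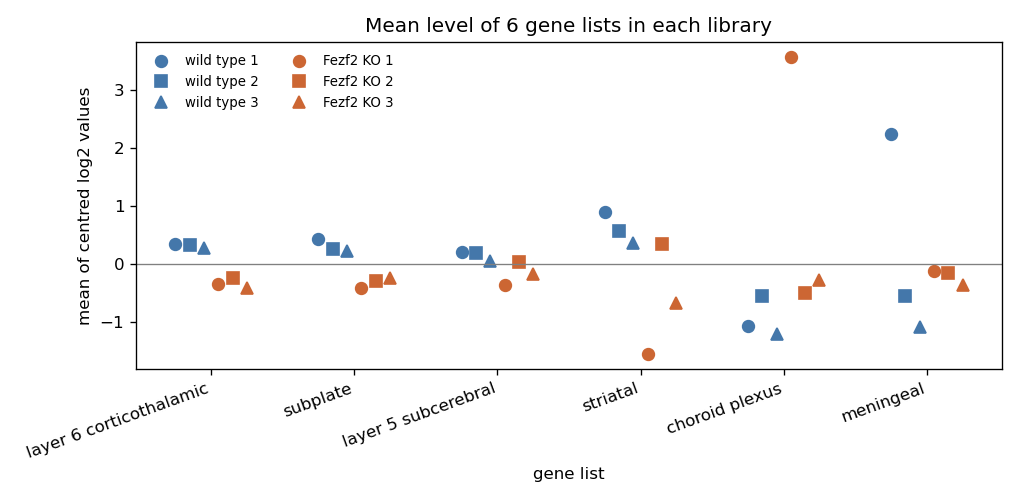
Mean over the members of 6 gene lists of the log2 value, each gene centred on its mean over the 6 libraries, with 1 point per library (colour for genotype, shape for replicate). Corticothalamic values lie at 0.28 or above in wild type and at -0.24 or below in Fezf2 KO libraries, while the choroid plexus value of Fezf2 KO 1 is 3.57.

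Callosal and upper-layer genes, which mark neurons that project within the cortex, were higher as a group by camera (adjusted p = 1.86e-05, and adjusted p = 0.34 with an estimated correlation). Of 25 tested, 1 rose and 0 fell (5 higher and 1 lower adjusted over the list alone, and by limma with litter as a block 2 higher). Mdga1, a cell adhesion protein, rose from 10436 ± 989 to 16817 ± 1016 (log2 0.69, SE 0.075, limma adjusted p = 0.00594), while Cux2 (log2 0.14) did not pass. With litter as a block, Epha3 was the added gene, and without Fezf2 KO 2 Lpl joined Mdga1 to give 2 higher members. GABAergic interneuron genes were also higher by camera (adjusted p = 0.000316, and adjusted p = 0.34 with an estimated correlation), with 2 of 19 risen and 0 fallen (6 higher adjusted over the list alone). Npy, neuropeptide Y, rose from 4343 ± 377 to 7025 ± 1121 (log2 0.69, SE 0.112, limma adjusted p = 0.0402, and 0.0686 with litter as a block). Sp8, a zinc finger transcription factor, rose from 1087 ± 73.5 to 1465 ± 58.8 (log2 0.43, SE 0.073, limma adjusted p = 0.0457, edgeR 0.06). Neither gene passed limma without wild type 1, 2 or 3 or without Fezf2 KO 3, where 0 members changed, and without Fezf2 KO 1 it was Npy alone that passed. Without Fezf2 KO 2 Npy passed, and Sp8 had an adjusted p of 0.124 in limma.

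Among 16 neuropeptide genes 2 rose (Cck and Npy) and 2 fell (Adcyap1 and Trh), and adjusted over the list alone 2 were higher and 7 lower. Adcyap1, which encodes the peptide PACAP, fell from 406 ± 6.86 to 184 ± 27.7 (log2 -1.15, SE 0.128, limma adjusted p = 0.00628). Trh, thyrotropin releasing hormone, fell from 153 ± 37.4 to 64.6 ± 4.88 (log2 -1.20, SE 0.202, limma adjusted p = 0.0445). Camera gave the list an adjusted p of 0.0449 in the lower direction, and adjusted p = 0.591 with an estimated correlation. That adjusted p was 0.0693 without wild type 1, 0.0627 without wild type 2, 0.218 without Fezf2 KO 1 and 0.0534 with RLE size factors. The mean of the centred log2 values of the list was -0.75, 0.07 and -0.09 in Fezf2 KO 1, 2 and 3, against 0.30, 0.24 and 0.23 in wild type 1, 2 and 3. Penk and Tac1, the latter chosen after its values were seen, belong to the striatal list as well. With the striatal mean as a covariate in limma, the log2 change of Penk went from -1.35 to -0.53 and that of Tac1 from -1.64 (SE 0.514) to -0.10 (SE 0.17). With litter as a block, as without wild type 1, without wild type 3 and without Fezf2 KO 3, 1 member was higher and 1 lower. Of these 16 genes, 1 was higher and 2 lower without wild type 2, 2 were higher and 1 lower without Fezf2 KO 1, and 2 were higher and 4 lower without Fezf2 KO 2. Limma's adjusted p of Trh lay between 0.0972 and 0.171 without each library other than wild type 2.

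Axon guidance and adhesion genes held 2 falls and 0 rises among 44 tested (5 higher and 4 lower adjusted over the list alone), and camera did not pass (adjusted p = 0.25). Ephb1, an ephrin receptor, fell from 8159 ± 622 to 4596 ± 544 (log2 -0.83, SE 0.091) and Flrt2, a ligand of Unc5 receptors, fell from 2202 ± 137 to 1437 ± 49.3 (log2 -0.61, SE 0.067), both with a limma adjusted p of 0.00594. Without Fezf2 KO 2 Sema3e joined them, giving 3 falls. Of 12 glutamatergic neuron genes 1 rose, both over all genes and adjusted over the list alone. It was Slc17a6, the vesicular glutamate transporter VGLUT2, with 961 ± 30.2 against 664 ± 48.9 (log2 0.54, SE 0.080, limma adjusted p = 0.0276). Camera gave this list an adjusted p of 0.25, and 0.0129 without Fezf2 KO 1. The rise of Slc17a6 did not pass limma without any 1 of the 6 libraries (adjusted p from 0.0542 to 0.127). Among 12 immediate early genes 1 rose (2 adjusted over the list alone, and with litter as a block in limma 2, Junb and Egr2). Egr2, an activity-regulated zinc finger gene, reached 186 ± 16.2 against 87.4 ± 10.6 (log2 1.09, SE 0.141, limma adjusted p = 0.0137). Its adjusted p in limma was 0.0651 without wild type 3, 0.0507 without Fezf2 KO 2 and 0.0669 without Fezf2 KO 3. Camera gave the immediate early list an adjusted p of 0.00581 in the higher direction (0.374 without Fezf2 KO 2), and adjusted p = 0.455 with an estimated correlation.

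In the 15 lists with 0 genes changed by limma, striatal genes included, 152 genes were tested, 26 of them had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 3 (Pdgfra, Penk and Fibcd1). Oligodendrocyte lineage genes were higher as a group by camera (10 tested, adjusted p = 0.018, and adjusted p = 0.394 with an estimated correlation), with Pdgfra at 3657 ± 116 against 3198 ± 39.0 as the 1 member higher adjusted over the list alone and Mag at 189 ± 19.1 against 146 ± 26.0. That adjusted p was 0.158 without Fezf2 KO 2 and 0.0653 without Fezf2 KO 3. Endothelial and mural cell genes were higher by camera as well (11 tested, adjusted p = 0.0154, and adjusted p = 0.591 with an estimated correlation), with Kcnj8 at 460 ± 38.1 against 382 ± 4.35 and Tek at 324 ± 15.7 against 261 ± 31.7. Without wild type 3 it was 0.619, and without Fezf2 KO 1 it was 0.0773. Astrocyte genes were lower by camera (10 tested, adjusted p = 0.00386, and adjusted p = 0.34 with an estimated correlation), with Agt at 5.25 ± 2.52 against 18.3 ± 9.59 and Id3 at 1637 ± 182 against 1927 ± 115. It was 0.0558 without Fezf2 KO 1.

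Lists of other cells and states did not pass camera with all libraries. Radial glia and proliferation genes had an adjusted p of 0.706 over 18 tested (median log2 0.02 and mean 0.00), with Ccnd2 at 6762 ± 705 against 7641 ± 833 and Emx2 at 745 ± 18.8 against 687 ± 22.1. Intermediate progenitor genes had 0.797 over 8 tested, with Elavl2 at 2138 ± 70.1 against 2000 ± 72.2 and Gadd45g at 716 ± 40.3 against 789 ± 57.6. Cajal-Retzius cell genes had 0.409 over 7 tested, with Lhx5 at 299 ± 75.5 against 273 ± 34.1 and A930038C07Rik at 523 ± 95.7 against 414 ± 81.5. Voltage-gated channel genes had 0.409 over 28 tested (0.000807 in the higher direction without Fezf2 KO 1), with Kcnc1 at 5215 ± 85.6 against 4729 ± 85.2 and Cacna2d1 at 2358 ± 51.7 against 2145 ± 22.3. Microglia genes had 0.0949 over 10 tested (0.0101 in the lower direction without wild type 3), with Cx3cr1 at 556 ± 60.3 against 638 ± 75.1 and Fcer1g at 43.2 ± 11.1 against 55.5 ± 4.91. Hypoxia and glycolysis genes had 0.383 over 11 tested, with Aldoa at 11250 ± 664 against 12770 ± 388 and Slc2a1 at 3066 ± 233 against 2692 ± 271. Heat shock genes had 0.706 over 7 tested, with Hspa1a at 568 ± 28.6 against 714 ± 115 and Hspa1b at 1079 ± 92.5 against 1223 ± 177, a pair of near-identical genes whose reads cannot be assigned with certainty.

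Markers of neighbouring tissues differed between single libraries. Ttr, the transthyretin of choroid plexus, stood at 8950 in Fezf2 KO 1, at 65.6 and 68.0 in Fezf2 KO 2 and 3, and between 9.45 and 15.7 in wild type, and Folr1 stood at 283 in Fezf2 KO 1 and between 4.30 and 15.9 elsewhere. Camera gave the 4 tested choroid plexus genes an adjusted p of 0.12, with 0.0249 and 0.0394 in the higher direction without Fezf2 KO 2 and 3, and without Fezf2 KO 1 Ttr rose by limma (log2 2.33, adjusted p = 0.0173). Meningeal fibroblast genes stood out in wild type 1, where the collagen gene Col1a2 had 2336 and Col3a1 had 1904, against 211 to 297 and 73.1 to 150 elsewhere. Their adjusted p by camera was 0.383 over 5 tested, 0.00182 in the higher direction without wild type 1 and 0.0122 in the lower direction without wild type 3. Erythroid genes had 0.706 over 5 tested, in the lower direction and with a median log2 of -0.06 but a mean of 0.06, and 1.94e-05 in the lower direction without Fezf2 KO 1. Hba-a2, an alpha globin copy, had 8191 ± 1771 against 8701 ± 762, and Slc4a1 had 286 in Fezf2 KO 1 and 4.49 to 22.3 elsewhere. Thalamic genes had 0.352 over 7 tested in the higher direction (median log2 -0.03, mean 0.06), with Slc17a6 as the 1 gene that rose, also adjusted over the list alone. Hippocampal genes had 0.0687 over 6 tested, with 1 higher adjusted over the list alone, and 0.0377 without wild type 2 and 0.00586 without Fezf2 KO 1, both in the higher direction. Fibcd1 had 1837 ± 532 against 890 ± 203 (limma adjusted p = 0.133, and 0.0238 without Fezf2 KO 1), and Prox1 had 742 ± 37.4 against 643 ± 52.9. Olfactory bulb genes had 0.059 over 5 tested in the lower direction (0.0489 with litter as a block, 0.0457 without wild type 3 and 0.0211 without Fezf2 KO 2), with Trh as the 1 gene that fell, also adjusted over the list alone. With both wild type 1 and Fezf2 KO 1 left out, an alternative chosen after seeing the data, limma called 57 genes, 28 higher and 29 lower, of which 40 were among the 125.

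Xist, the transcript of the inactive X chromosome, stood at 3782 in wild type 2 and at 2.81 or below in the other libraries, and the Y-linked Ddx3y stood at 2.62 in wild type 2 and between 376 and 452 elsewhere. The genotypes were therefore not matched for this marker of sex. Within 10 Mb of Fezf2, by the gene positions of the mouse assembly GRCm38, 1 of 82 tested genes changed, against 111 of 14611 elsewhere (1.22% and 0.76%, odds ratio 1.61, 95% interval 0.04 to 9.43, two-sided Fisher exact p = 0.467). The 1 gene was Gm6676, chosen after its values were seen, a predicted gene of a multi-copy family whose reads are uncertain, with 2.32 ± 1.05 against 93.9 ± 21.9 (limma adjusted p = 0.000372). With the calls of DESeq2, an alternative chosen after seeing the data, the odds ratio was 7.61 (Fisher exact p = 1.09e-07). Of the 13 calls near Fezf2, however, 11 were copies of predicted genes that may share reads and cannot be taken as independent. With predicted genes left out, which was chosen after seeing the data, 2 of 54 were called by DESeq2 near Fezf2 against 331 of 13419 elsewhere (odds ratio 1.52, 95% interval 0.18 to 5.82, Fisher exact p = 0.387).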

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

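The edgeR fits without a filter and with litter as a block, the fit without both wild type 1 and Fezf2 KO 1, and the genes near Fezf2 under other calls were chosen only after the results were seen. Genes changed (125, with 71 higher and 54 lower) numbered 119 to 138 under a pseudocount of 0.5, no filter, 4 edgeR fits, limma-voom and litter as a block in limma or edgeR, and 124 without Fezf2 and sex-linked genes. They numbered 403 by DESeq2 (242 higher, 161 lower, all 125 among them), and the cause was not tested. With fewer libraries there were 29 (12 and 17) in litter m1 alone and 57 (28 and 29) without wild type 1 and Fezf2 KO 1. By construction a minimum change of 1.2-fold gave fewer, 48 (17 and 31), and an adjusted p threshold of 0.1 gave more, 222 (128 and 94). Leaving out 1 library gave 61 (Fezf2 KO 3) to 119 genes changed, 21 (Fezf2 KO 3) to 55 higher and 37 to 73 lower. The genes called also differed. Of the 125, 56 were called again without Fezf2 KO 3, 68 without wild type 1 and 86, the most, without Fezf2 KO 1. Litter as a block in limma changed no call of a named gene or list other than those given with their values. In edgeR it ended the calls of Otx1 (adjusted p = 0.0514), Npy (0.0707) and Trh (0.0599). Lists past camera numbered 11, 12 with litter as a block, 10 with RLE factors and 11 to 13 without 1 library. Lists that passed numbered 2 by fry, which compares with no other genes, and 0 by camera with an estimated correlation. For the 11 lists the estimates ran from 0.043 (corticothalamic genes) to 0.788 (striatal genes), all above the preset correlation of 0.01. Their adjusted p at the preset correlation may therefore be too small. The log2 change of Fezf2 was -1.72 in litter m1 alone (limma adjusted p = 0.0595, with fewer libraries) and from -1.90 to -1.64 without 1 library. The odds ratio of changed genes near Fezf2 was 1.61, with 1.45 from litter as a block, 3.39 from edgeR, 7.61 from DESeq2 and 1.52 from DESeq2 with predicted genes left out, whose copies made 11 of its 13 calls there. Of 67 named genes besides Fezf2, 37 changed; 10 passed in each of 19 alternatives, 26 did not pass in litter m1 alone, and 23 passed without each library in turn.

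Depth limits the genes with few reads, as 11 of the 125 had a mean under 50. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many genes; the highest other gave 1 gene, also among the 6 splits that part the litter m2 libraries, and 10 splits are too few for a share under 0.05. The criterion set down beforehand for sex of the pups, Xist in libraries of both genotypes or of none, was not met, since only wild type 2 had it. Sex was instead tested with the 5 libraries that lacked Xist. Limma called 77 genes there, 69 of them among the 125, which argues against sex as the whole cause. The other 56 lost their call with fewer libraries. The median of their log2 changes, each in its own direction, went from 0.60 (quartiles 0.44 to 0.86) to 0.58 (0.44 to 0.90). Each gene held 85.2% or more of its change (a test chosen after seeing the data). Since the genotypes of all 125 were fully separated with wild type 2 included, a large loss was unlikely in advance, so this gives no verdict on sex for the 56.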

Other observations

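The tests on predicted genes near Fezf2, both tests on Pax7, the order of Fezf2 KO libraries in other lists and the count of neighbouring genes were chosen only after the result was seen; those on striatal genes and on separated genes near Fezf2 were set down before. The genes of the next sentences were chosen after their values were seen, and no theme was tested. By limma, rises were found for Msx3, a homeobox gene of the dorsal neural tube (1130 ± 255 against 482 ± 49.0, log2 1.21, adjusted p = 0.013), Sp5, a Wnt target gene (346 ± 60 against 164 ± 29.1, log2 1.08, adjusted p = 0.0393), Frzb, a secreted Wnt antagonist (272 ± 12 against 145 ± 18.5, log2 0.91, adjusted p = 0.0183), and Nog, the BMP antagonist noggin (1672 ± 296 against 982 ± 57.7, log2 0.75, adjusted p = 0.0399). Gdf10, a BMP-family ligand, fell from 1782 ± 96.6 to 934 ± 89.8 (log2 -0.93, limma adjusted p = 0.00289), and Rgma, a BMP co-receptor and repulsive guidance molecule, fell from 21307 ± 1519 to 15753 ± 269 (log2 -0.43, limma adjusted p = 0.0111).

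Further rises by limma were those of Rgs8, a regulator of G protein signalling, from 2444 ± 228 to 4719 ± 190 (log2 0.95, adjusted p = 0.00106), Chrm2, a muscarinic receptor, from 188 ± 20.6 to 355 ± 32.1 (log2 0.92, adjusted p = 0.0157), and Grm2, a metabotropic glutamate receptor, from 3930 ± 250 to 5634 ± 614 (log2 0.52, adjusted p = 0.0431). Nptx1, a neuronal pentraxin, fell from 2317 ± 109 to 1096 ± 255 (log2 -1.11, limma adjusted p = 0.0203), and the sorting receptor gene Sorcs1 fell from 1208 ± 121 to 663 ± 46.7 (log2 -0.86, limma adjusted p = 0.00594). Among 2099 assembled noncoding transcripts tested, 12 changed. Of the 105 changed genes with a known place among 13342, 9 pairs lay at most 3 places apart in gene order, 6 of them changed in the same direction, such as Nxph3 with Ngfr, against a mean of 2.42 pairs and a highest of 11 in 10000 expression-matched random sets (permutation p = 4e-04).

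Striatal genes were low in Fezf2 KO 1 and 3 and nearer to wild type in Fezf2 KO 2, with means of -1.55, -0.66 and 0.36. In a second list of 10 striatal genes, 8 put the Fezf2 KO libraries in the same order (80%, exact binomial 95% interval 44.4 to 97.5). That interval treats the genes as independent, which genes of 1 tissue read in the same libraries are not. Over all 17557 tested genes the share in this order was 19.1%. The second list fell less than the first, with a median log2 of -0.23 against -1.31, and 7 of its 10 genes were lower in Fezf2 KO. The same order held for 75% of the 12 immediate early genes and 50% of the 28 voltage-gated channel genes. Unequal striatal tissue among the Fezf2 KO dissections therefore cannot be told apart from another difference between these libraries. Less striatal tissue as the whole cause of the 125 changed genes was tested with the striatal mean as a covariate in limma. The median change in each gene's own direction went from 0.86 (quartiles 0.56 to 1.49) to 0.80 (0.50 to 1.39), or 92.6%. It was 83.8% for the lower genes and 77.0% for the 11 corticothalamic and subplate genes, 7 of which stayed past the threshold. Of the 125, 28 stayed past the threshold. The covariate differs between the genotypes and takes a degree of freedom, and some changes shrank. Which of these ended the other calls was not tested. The striatal mean varied widely among Fezf2 KO libraries, so genes that follow it were unlikely to be called, and 0 of the 12 striatal genes were. The share kept was therefore largely set by the choice of genes. It shows that the 125 changes, as a set, followed the striatal mean little, but it is no independent evidence against the tissue as a cause. Tle4 went from -1.69 (SE 0.061) to -1.60 (0.081) and Foxp2 from -1.74 (0.187) to -1.24 (0.144), both still past the threshold, whereas Bcl11b went from -0.84 (0.182) to -0.29 (0.061) and Crym from -2.22 (0.655) to -0.51 (0.533), so for the latter pair the tissue stays an open explanation. An effect of the genotype on striatal genes that varies between pups stays open and untested.

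Near Fezf2, 14 of 54 named genes had fully separated genotypes (25.9%) against 14.1% of 13419 elsewhere, with an odds ratio of 2.13 (95% interval 1.07 to 4, Fisher exact p = 0.0187). Neighbouring genes read in the same libraries are not independent, so this p may be too small. DNA of a stem cell strain flanking the targeted allele may explain the excess, but the origin of the allele is not given. For the changed genes, with 1 of 82 and an odds ratio of 1.61, flanking DNA and no such effect cannot be told apart, because the interval from 0.04 to 9.43 holds both. Of 28 entries for predicted genes there, 22 were separated, 20 of them higher in Fezf2 KO, against 12.8% of 1192 elsewhere, and the 22 include all 20 Gm-numbered entries, which carry 7 symbols. Reads merely passed among these Gm-numbered copies would leave their sum equal, if reads matching several copies were counted and no copy lay outside the 20 entries. The sum was 2765 ± 172 in Fezf2 KO and 1554 ± 352 in wild type, with a gap of 619 between the lowest Fezf2 KO and the highest wild type library. The alignment settings are not given, so the sum cannot decide whether reads were assigned differently among the copies. The copies may share reads and cannot be taken as independent, and an effect of Fezf2 loss on its neighbours stays open.

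Pax7 had 305 ± 29.6 in Fezf2 KO and 1.21 ± 1.05 in wild type cortex. Dorsal midbrain tissue in the Fezf2 KO dissections would bring its other transcripts. Among 7 other genes of that tissue the highest ratio of the Fezf2 KO mean to the wild type mean plus 1 was 2.78, for Barhl1 with means of 15.7 and 4.65. Barhl1 did not overlap between genotypes (14.1 to 18.7 against 0.94 to 6.98), and its Fezf2 KO mean was the highest of the 7. Fezf2 KO means were also above wild type for En1 (4.62 against 2.68), En2 (9.28 against 6.75), Gata3 (5.76 against 5.32) and Pou4f1 (6.36 against 5.28). Pax3 had 0.29 in both genotypes, and Lmx1b was lower (0.57 against 2.16). Levels of these 7 genes beside Pax7 in dorsal midbrain are not known here, so such low values cannot decide on that tissue. Reads shared with its paralog Pax3 are argued against, since Pax3 held 0.1% of the Pax7 value in Fezf2 KO libraries. Transcription of Pax7 in Fezf2 KO cortex itself may be the source, as a hypothesis found and tested on the same data, and dorsal midbrain tissue stays open. Tissue of other regions that express Pax7 was not tested.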
